A study of Acetivibrio thermocellus DSM 1313 with 8 samples.

How the data were processed

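RNA sequencing of 8 samples of bacterial culture was analysed, 4 of a Clostridium thermocellum strain called wild type, which per the labels carries a deletion of hpt, and 4 of a strain in which the type I glutamine synthetase gene Clo1313_2031 was deleted. Per the labels' protocols, total RNA was extracted with TRIzol and bead beating, treated with DNase, depleted of ribosomal RNA with a Ribo-Zero kit for Gram-positive bacteria, made into libraries with a ScriptSeq kit and sequenced as short single reads on an Illumina HiSeq instrument. The labels used here do not state whether the deletion strain also carries the hpt deletion. Samples were assigned to the groups by the strain in their labels. The replicate number came from the same label.

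The deposited table of counts holds whole, unnormalized read counts per gene for the 8 libraries, and each column was matched to its sample by strain and number. It held 0 count columns of no sample. The submitters' processing notes name bcl2fastq 1.8.3, DESeq and DESeq2, with no role given for any of them. The aligner, the counting tool and its strand setting, the genome build and the annotation were not given in the sources used here. It was therefore not known how reads shared by similar genes, or reads from genes that overlap on opposite strands, had been assigned. Ribosomal and transfer RNA genes, which have near-identical copies, are uncertain for this reason. Per the file headers, the authors' deposited comparison table gives a mean normalized signal per gene, without saying how it was normalized. Per the file headers, the same deposited table gives log2 fold changes of deletion over wild type with their standard errors. P-values and adjusted p-values stand beside them in that deposited table, per the file headers. A further deposited sheet lists 152 genes past an adjusted p-value of 0.05 and a 2-fold limit and pairs each with a product description. The other sheets repeated the first sheet or parts of it and were not used here.

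The table had 3103 genes, of which 3031 were numbered locus tags, 69 were numbered tags of the ribosomal and transfer RNA type (R tags), and 3 were the RNA genes ssrA, rnpB and ffs. Genes at 0 in every library numbered 55. The function filterByExpr of edgeR kept 2954 genes and left out 149. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (robust settings, two-sided), and p-values were adjusted by Benjamini and Hochberg's method over the 2954 genes. A gene was called at an adjusted p under 0.05, and called 2-fold at an absolute log2 fold change of at least 1 besides. Expression is given as CPM, counts scaled to library size, after TMM scaling, with the SD over 4 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of F. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. No genome or annotation was used here, so neighbouring genes are those with consecutive locus tag numbers, and their strand, distance and length were not analysed here.

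The groups, the tests of the comparison of the strains, the gene lists, the rule for named genes and the alternatives, apart from the 1 named below as added, were chosen before the data were examined. The family counts and most tests of explanations in the closing section were chosen after results were seen, as said where they are given. The rule named the deleted gene with 4 locus tags on each side, and the 10 largest rises and 10 largest falls among called genes whose mean was at least 10 CPM and whose groups did not overlap. It also named up to 4 called members per gene list with the smallest p-values, and every gene described as a glutamine synthetase, glutamate synthase, glutamate dehydrogenase, nitrogen regulatory protein P-II, ammonium transporter, or alcohol, lactate or aldehyde-alcohol dehydrogenase. Where other genes are named, the text says that they were chosen after their values were seen. The rule also covered the hpt gene, which was not analysed here because the product descriptions used here do not name it.

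Gene lists were drawn by matching words in product descriptions. Descriptions were used for the 152 genes of the authors' sheet alone, and these had been selected for changing in the same 8 libraries. The planned competitive gene set tests (camera, with fry as an alternative) need descriptions of unchanged genes too and were not run. Of 18 lists, 9 had a described member, and the other 9 had none. The empty lists were arginine biosynthesis, branched-chain amino acid biosynthesis, aromatic amino acid and histidine biosynthesis, sulfur, cysteine and methionine metabolism, purine and pyrimidine biosynthesis, flagella and chemotaxis, ATP synthase, sugar ABC transporters, and cofactor and vitamin biosynthesis. A list with 0 described members says nothing about whether its genes changed by less than 2-fold.

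Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Library pairs within a group differed by far more than sampling noise, with chi-square values of 50.3 to 204 per degree of freedom, so no library was counted as a copy of another. Total counts ran from 11372177 to 22969265 per library.

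The test was tried on simulated data, with counts drawn for the 2954 genes of the comparison of deletion with wild type and 200 genes changed by known factors. In that simulation edgeR recovered 43 of 77 genes changed 1.5-fold, 50 of 60 changed 2-fold and 63 of 63 changed 4-fold, with 4 false calls (2.5% of calls). DESeq2 made 15 false calls there (8.52%) and limma-voom 4 (2.5%). Alternatives tried were DESeq2, limma-voom, RLE and total-count scaling, no filter on low counts and a strict one (10 CPM in 4 libraries), the replicate number as a block, leaving out the R tags, leaving out each library in turn, a test against a 1.5-fold limit, and the share of the deleted gene without the 10 most abundant genes. The fold of pooled reads of the deleted gene without each library in turn was added after seeing the data.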

Results

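Transcripts of Clostridium thermocellum, an anaerobic, thermophilic bacterium that degrades cellulose, were compared between a strain lacking the type I glutamine synthetase gene Clo1313_2031 and the hpt-deleted strain called wild type. The labels give the hpt deletion for the wild type samples and do not state it for the deletion strain, so the strains may also have differed at hpt. Both were grown in 50 ml batch cultures of MTC medium with 4.5 g/l cellobiose at an initial pH of 7.2 and sampled in mid-exponential phase at an optical density of about 0.33. Each group had 4 libraries. Total counts were 14951635, 17201917, 15674767 and 11372177 in wild type replicates 1 to 4 and 12852848, 19540966, 22969265 and 13592124 in deletion replicates 1 to 4. Library pairs correlated at 0.989 to 0.996 within wild type, 0.981 to 0.994 within the deletion strain and 0.953 to 0.972 between the strains (Pearson's r of log2 CPM across genes, which are not independent replicates). The first principal component held 66.7% of the variance and separated the strains, and the second, with 11.7%, set deletion replicate 2 (15.5) furthest from deletion replicate 4 (−11.6). Deletion replicate 2 also had the highest share of counts on R tags, 0.404%, against 0.111% to 0.232% in the other deletion libraries and 0.0853% to 0.130% in wild type.

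The deleted gene, which encodes an enzyme that makes glutamine from glutamate and ammonia, was read first in every library as a check of the strains. Clo1313_2031 had 5787, 6864, 4543 and 3863 reads in wild type replicates 1 to 4 and 8, 3, 1 and 15 reads in deletion replicates 1 to 4. These corresponded to 354 ± 49.8 CPM of the total count in wild type and 0.481 ± 0.485 CPM in the deletion strain (SD, n = 4 each). Pooled over libraries, 21057 reads stood against 27, a level 908-fold lower in the deletion strain (95% exact interval 624 to 1379, counting error only). Deletion replicate 4 held 15 of those 27 reads, and without it the level was 1641-fold lower, outside that interval, which does not cover the spread between libraries. The labels of all 8 libraries therefore matched the reads at the deleted locus. Where within the gene the remaining reads lay was not analysed here.

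Genes on both sides of the deleted locus were also higher in the deletion strain. Clo1313_2034 (iron-sulfur cluster-binding protein) and Clo1313_2035 (glutamate synthase, which makes glutamate from glutamine and 2-oxoglutarate), both numbered shortly after it, rose by 5.69 ± 0.22 and 5.48 ± 0.15 on the log2 scale (SE, n = 4 per group). Closer to the deletion the rises were smaller: Clo1313_2030, Clo1313_2032 and Clo1313_2033, which have no product description here, rose by 0.98 ± 0.14, 0.94 ± 0.15 and 0.83 ± 0.12. Adjusted p-values of these 5 genes ran from 2.77e-10 to 0.000719 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On the lower-numbered side, Clo1313_2027 and Clo1313_2029 passed narrowly by the same test, with log2 fold changes of 0.38 and 0.51 and adjusted p-values of 0.0497 and 0.0440. Clo1313_2028 did not pass, with a log2 fold change of 0.20 ± 0.10 and an adjusted p of 0.141 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The calls of Clo1313_2027 and Clo1313_2029 each ended in 6 of the 8 fits that left out 1 library. For Clo1313_2027 these were the fits without wild type replicate 1, 3 or 4 or deletion replicate 1, 2 or 4, and for Clo1313_2029 those without any 1 of the wild type replicates or without deletion replicate 2 or 3, with adjusted p-values over all 8 such edgeR fits of 0.0224 to 0.131 and 0.0271 to 0.102.

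Apart from the deleted gene, the largest changes across the genome were rises. Of 2954 genes tested, 956 (32.4%) were called, with 481 higher and 475 lower in the deletion strain. The balance of directions depended on the scaling: with total-count scaling in place of TMM, 525 were higher and 376 lower. Most of these changes were small: 781 were under 2-fold, and the median absolute log2 fold change of called genes was 0.63. At least 2-fold changes were found in 175 genes (5.92%), of which 104 rose and 71 fell. The 4 values of each strain did not overlap for 973 genes (32.9%), where chance gives 2.86%. Without deletion replicate 2, 869 genes were called and 157 were called 2-fold.

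The question of how nitrogen genes behaved without this glutamine synthetase was addressed with the genes described as belonging to nitrogen assimilation. Of 16 described members, 15 rose and 1 fell, and the 1 that fell was the deleted gene itself. The 3 largest rises by fitted log2 fold change among all genes tested were of these members. Clo1313_2303, described as a glutamine synthetase catalytic region, went from 1.73 ± 0.187 CPM in wild type to 167 ± 19.3 CPM in the deletion strain, a 96.2-fold rise (log2 fold change 6.59 ± 0.15). Clo1313_2038, also described as a glutamine synthetase catalytic region, went from 113 ± 10.7 to 1516 ± 150 CPM, a 13.4-fold rise (log2 fold change 3.74 ± 0.12). The ammonium transporter gene Clo1313_2260 rose 39.6-fold, from 9.57 ± 0.709 to 379 ± 59.9 CPM. Glutamate synthase Clo1313_2035 rose 44.6-fold, from 10.3 ± 1.43 to 462 ± 63.5 CPM, and Clo1313_2036, described as a class-II glutamine amidotransferase and not a member of the list by its description, rose 22.9-fold, from 29.6 ± 10.8 to 681 ± 99.2 CPM (SD, n = 4 per group throughout). Adjusted p-values of these 5 genes ran from 1.62e-10 to 4.26e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

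The described genes for the uptake and breakdown of urea rose. All 5 described genes of a urea ABC transporter, a membrane pump for urea, rose by 5.14 to 6.67 on the log2 scale. The urea binding protein gene Clo1313_2497 had the largest rise by fitted log2 fold change among the genes named by rule, 102-fold, from 1.75 ± 0.447 to 181 ± 21.6 CPM (SD, n = 4 each), and the permease gene Clo1313_2496 (UrtB) rose by 6.07 ± 0.17 on the log2 scale. The 6 described genes for urease, which splits urea into ammonia and carbon dioxide, and its accessory proteins rose by 2.93 to 4.07. The alpha subunit gene Clo1313_2490, chosen after its value was seen, went from 4.87 ± 0.905 to 62.2 ± 3.96 CPM. All these genes lie in 1 run of 14 consecutively numbered genes that each rose at least 2-fold, Clo1313_2486 to Clo1313_2499. The run ends with Clo1313_2498, described as a regulator of the AraC family, and Clo1313_2499, described as a hybrid histidine kinase, which rose by 2.80 ± 0.14 and 3.26 ± 0.12 and were also chosen after their values were seen. All 16 described members of the nitrogen list passed over all 2954 genes, and all 16 passed when adjusted over the list alone. Descriptions were used only for genes selected on these samples, and all 150 described genes tested were called 2-fold here. That the members passed therefore followed from the selection. Neither count is independent evidence of a change or of its direction, and described members alone were counted.

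**Figure D1:**
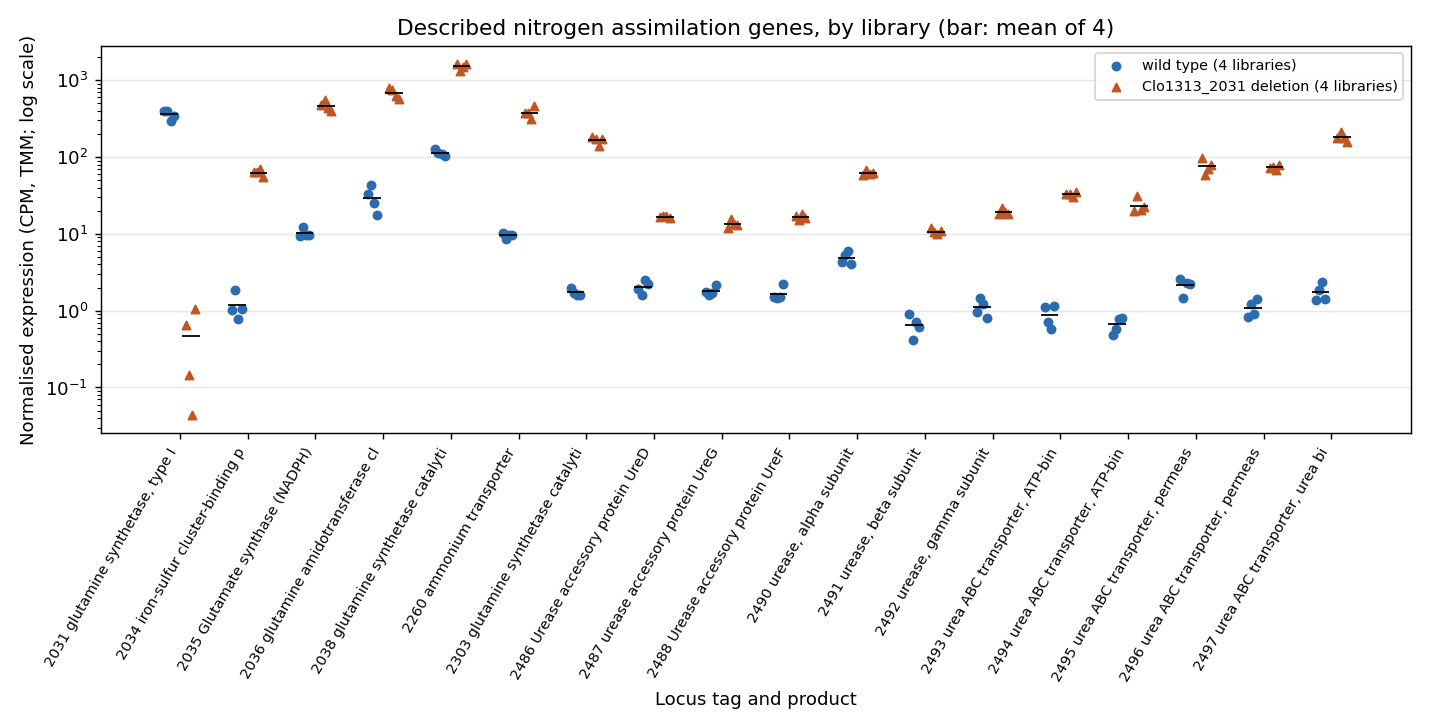
CPM after TMM scaling (log scale) of the 16 described nitrogen assimilation genes and of Clo1313_2034 and Clo1313_2036, with wild type libraries as circles, deletion libraries as triangles and the mean of 4 as a bar. The 4 deletion libraries lie above the 4 wild type libraries for every gene drawn except Clo1313_2031, the deleted gene, where they lie below.

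**Figure D2:**
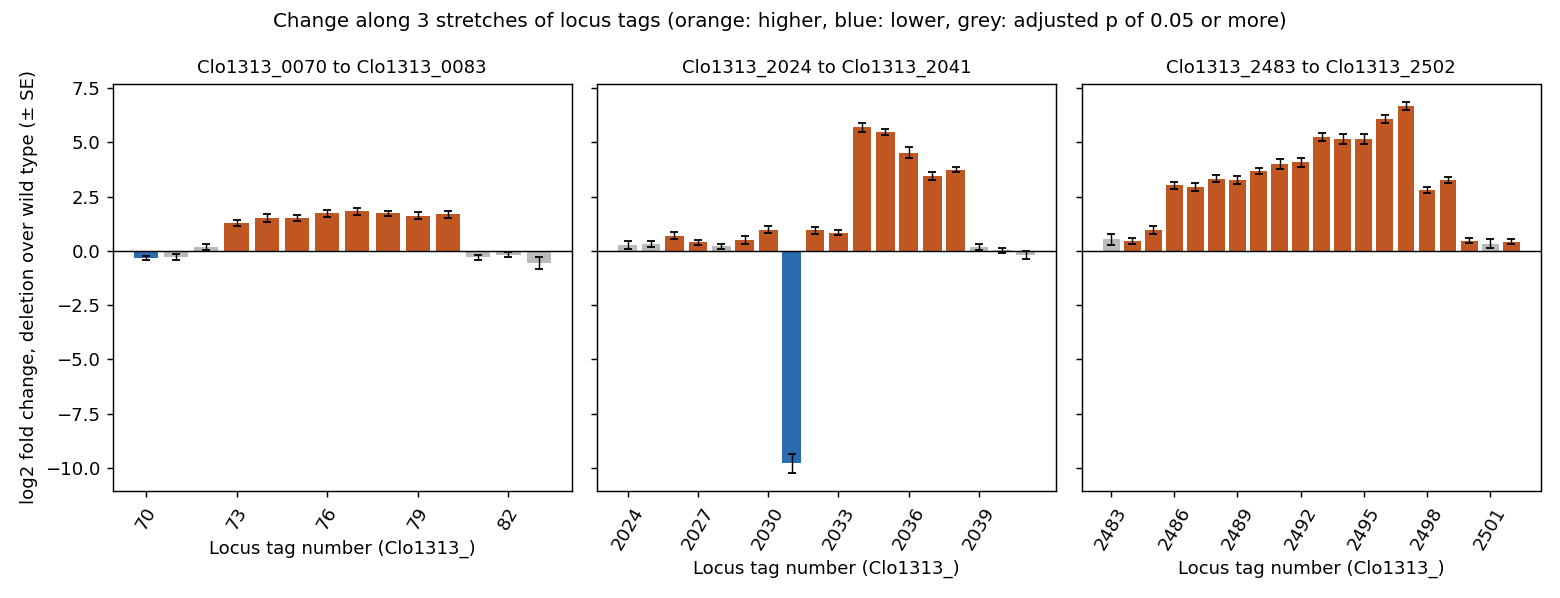
Log2 fold change of deletion over wild type (bars, ± SE) along 3 stretches of locus tag numbers, with called rises in orange, called falls in blue and genes that did not pass in grey. Between the deleted gene and the run Clo1313_2034 to Clo1313_2038 stand Clo1313_2032 and Clo1313_2033, with log2 fold changes of 0.94 and 0.83.

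Of 10 described members of the list of genes for glycoside hydrolases and the cellulosome, the enzyme complex that this bacterium uses to degrade plant cell walls, 9 fell and 1 rose, with a median log2 fold change of −1.38. All 4 genes described as cellulosome anchoring proteins with a cohesin region fell, including Clo1313_0627, from 7688 ± 829 to 2309 ± 359 CPM (3.33-fold), and Clo1313_0628, from 876 ± 235 to 198 ± 42.4 CPM (4.43-fold; SD, n = 4 each). Cohesins are binding modules of the cellulosome, some of which hold enzymes on the scaffold. The descriptions do not say what the cohesins of these 4 genes bind. The gene described as a family 48 glycoside hydrolase, Clo1313_2747, fell from 1782 ± 174 to 565 ± 24.7 CPM. Clo1313_2584, with a family 6 carbohydrate binding description, and Clo1313_0522, a family 11 glycoside hydrolase by description, had log2 fold changes of −1.52 ± 0.09 and −1.51 ± 0.13. The 1 member that rose, the family 5 glycoside hydrolase Clo1313_1425, was chosen after its value was seen and had a log2 fold change of 1.14 ± 0.13. All 10 passed over all 2954 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 10 when adjusted over the list alone, with the same limit of a list described on these samples. Genes that changed by less than 2-fold could not enter the list, so its median is not that of all cellulosome and glycoside hydrolase genes.

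Several other transcripts fell, some of them abundant and some not. Clo1313_2176, with an S-layer domain, the type of domain that binds proteins to the outer cell layer, had the largest fall among the genes named by rule apart from the deleted gene, from 429 ± 54.7 to 96.3 ± 10.5 CPM (log2 fold change −2.16 ± 0.12). Clo1313_0013, with a copper amine oxidase-like domain, had a log2 fold change of −2.13 ± 0.09 from a wild type level of 1653 ± 71.9 CPM, and Clo1313_1021, with a PKD domain, fell from 1931 ± 170 to 557 ± 30.2 CPM. Clo1313_2101 (phosphopantetheine-binding protein), Clo1313_1909 (hypothetical protein), Clo1313_1982 (MutS domain protein of DNA mismatch repair) and Clo1313_3020 (hypothetical protein) had log2 fold changes of −2.02 ± 0.29, −1.96 ± 0.13, −1.82 ± 0.14 and −1.78 ± 0.13. Families counted after their values were seen gave 6 of 6 described copper amine oxidase-like genes lower, 4 of 4 described genes of type II secretion systems lower (−1.21 to −1.06), and 3 of 4 described S-layer genes lower, while the S-layer gene Clo1313_0084 rose by 1.10 ± 0.11. Set against the directions of the other described genes by Fisher's exact test (two-sided), none of 13 families counted passed after adjustment over the 13. Adjusted p-values of that test were 0.0907 for the copper amine oxidase-like genes, 0.123 each for the type II secretion, cohesin and urease families, 0.170 for the urea transporter, 0.412 for the Rnf complex and 0.422 for the S-layer genes. For 4 members the strongest outcome, all 4 lower, gave an unadjusted p of 0.0378 by that test. Families this small could hardly pass. Neighbouring genes were counted as separate members besides, so the test does not decide whether directions were shared. Every gene in this paragraph passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

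**Figure D3:**
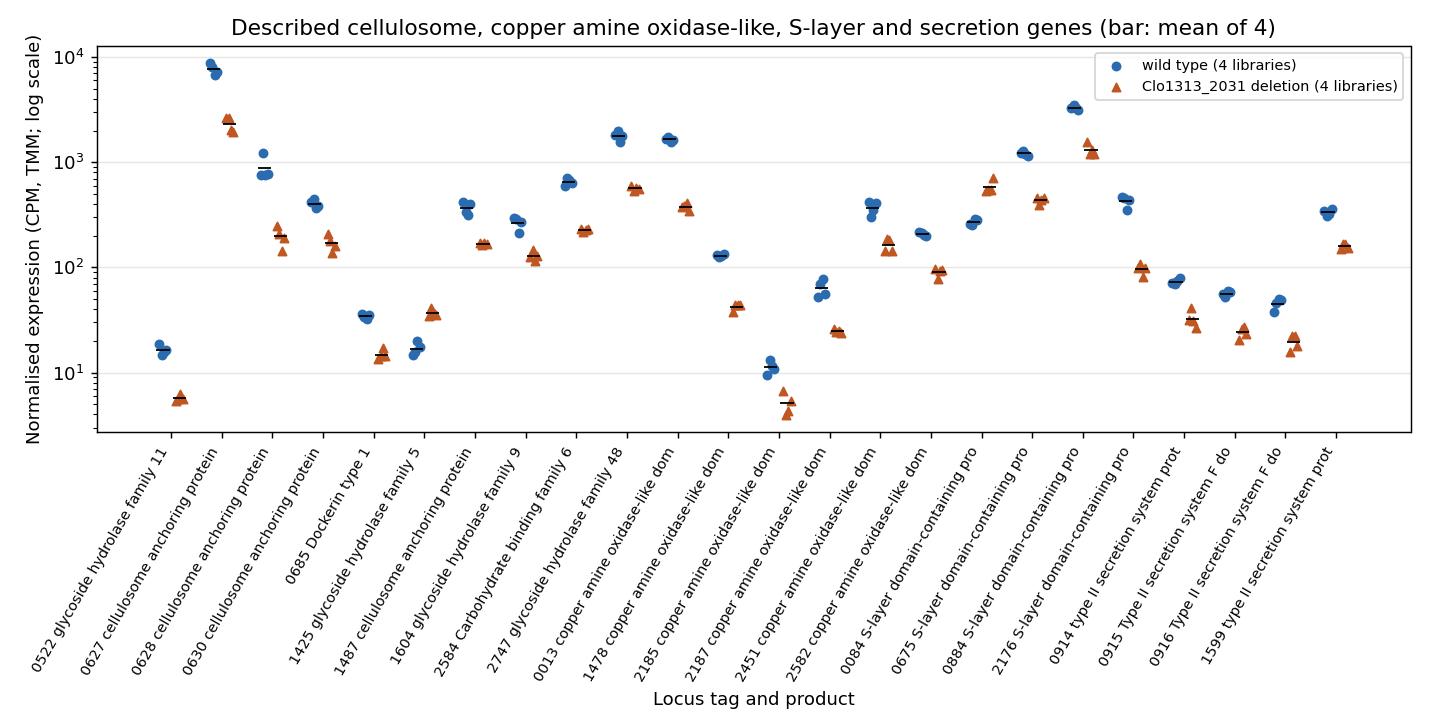
CPM after TMM scaling (log scale) of described cellulosome and glycoside hydrolase, copper amine oxidase-like, S-layer and type II secretion genes, with wild type libraries as circles, deletion libraries as triangles and the mean of 4 as a bar. The deletion libraries lie below the wild type libraries for all of these genes except Clo1313_1425 and Clo1313_0084, which rose by 1.14 and 1.10 on the log2 scale.

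The few described members of the electron transfer, fermentation and glycolysis lists rose by smaller amounts. The list of hydrogenases and electron transfer had 3 described members, all subunits of an Rnf complex, a membrane complex that moves electrons from ferredoxin to NAD+ and pumps ions. All 3 rose and passed over all genes and when adjusted over the list alone, with the same limit of a list described on these samples. Clo1313_0066 (subunit B), Clo1313_0065 (subunit A) and Clo1313_0063 (subunit G) rose by 1.56 ± 0.11, 1.31 ± 0.14 and 1.05 ± 0.12 on the log2 scale, and Clo1313_0066 went from 154 ± 16.3 to 454 ± 46.0 CPM (SD, n = 4 each). A run of 8 consecutively numbered genes, Clo1313_0073 to Clo1313_0080, rose by 1.28 to 1.81. It holds Clo1313_0076, an alcohol dehydrogenase by description, at 1.73 ± 0.16, and Clo1313_0080, a phosphoglycerate mutase by description, at 1.67 ± 0.16. These 2 genes were the only described members of the fermentation and glycolysis lists, respectively. Both lie in the same run, so they do not show a rise of either pathway. The word GroES in the description of Clo1313_0076 also made it the only member of the chaperone list, although it is a dehydrogenase domain there. The other genes of the run, described as a carbohydrate kinase, transketolase domains, an ABC transporter protein, an inner-membrane translocator and a hypothetical protein, were chosen after their values were seen.

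Of the remaining lists, sporulation held Clo1313_0278 (stage V sporulation protein B), which rose by 1.55 ± 0.33, from 12.6 ± 2.11 to 36.4 ± 19.6 CPM. The ribosomal protein list held Clo1313_0959 (L25-like), which rose by 1.28 ± 0.27 at a low level, from 1.62 ± 0.333 to 3.93 ± 1.26 CPM. The list of transposases, phage and CRISPR genes held Clo1313_2385 (phage minor structural protein), which rose by 1.10 ± 0.22, and Clo1313_2976 (Cas6), which fell by 1.40 ± 0.22 on the log2 scale. Each of these described members passed over all genes and when adjusted over the list alone, with the same limit of lists described on these samples. The 4 described ribosomal RNA genes rose by 1.53 to 2.95, but at mean levels of at most 17.4 CPM after depletion of ribosomal RNA. The share of counts on R tags was 0.111% to 0.404% in the deletion libraries and 0.0853% to 0.130% in wild type. Of 4 described transfer RNA genes, 3 rose and 1 fell, and in each of the fits without wild type replicate 1 and without wild type replicate 3 only 3 of the 4 passed. Copies of ribosomal and transfer RNA genes share reads, so these values are uncertain.

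The authors' deposited table compared the same 8 libraries, so it is no independent evidence. An adjusted p under 0.05 was given in the authors' deposited table for 1063 genes, with 504 higher and 559 lower in the deletion strain. At 2-fold the authors' deposited table had 152 genes, 85 higher and 67 lower, against 175 by edgeR here. The 2-fold lists shared 150 genes, all 150 in the same direction, with 25 genes only in the edgeR list and 2 only in the authors' deposited table. Those 2 genes in the authors' deposited table, Clo1313_2397 (phage portal protein) and Clo1313_R0072 (16S ribosomal RNA), had been left out here by the filter on low counts. Log2 fold changes in the authors' deposited table and here had a Pearson r of 0.987 and a Spearman rho of 0.999 across 2954 genes, which are not independent replicates. For the deleted gene the authors' deposited table gave a log2 fold change of −4.46, against −9.80 by edgeR. DESeq2 with its prior on fold changes came within 0.01 of the log2 fold change in the authors' deposited table for 2495 genes (81.9% of those compared), with a median difference of 0.00284 and a largest difference of 0.998. Without that prior, DESeq2 gave 179 genes at 2-fold and a log2 fold change of −9.64 for the deleted gene. The 152 and 175 genes at 2-fold were therefore not counted at like limits.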

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

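The tests of all calls by other splits of the libraries, of deletion replicate 2 and of the genes beside the deletion were chosen only after the results were seen, while the test of 2-fold calls by other splits was chosen before its result was seen. Among 90 groups of 4 values, 3 held a value far from the others by Dixon's test, where chance gives about 4.5. Glutamate synthase Clo1313_2035 had 12.5 CPM in wild type replicate 2, against 9.39 to 9.77 CPM in the other wild type libraries. The cohesin gene Clo1313_0628 had 1228 CPM in wild type replicate 2, against 750 to 768 CPM in the others. The RNA gene ssrA had 2812 CPM in wild type replicate 4, against 2090 to 2161 CPM in the others.

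Chance assignment of libraries to strains was tested for both counts of calls. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the split by strain, gave as many as 956 called genes, and only 1 gave as many as 175 called 2-fold. The highest count among the other 34 splits was 0 in both cases by edgeR, with 8 to 276 genes at an unadjusted p under 0.05 against 1293 in the split by strain. The other splits mix strains within groups, which widens the spread and makes calls in them unlikely. The comparison of splits therefore cannot exclude chance as the source of either count.

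Deletion replicate 2 stood apart on the second principal component, in its share of R tags and in rnpB, at 2083 CPM against 724 to 1551 CPM in the other deletion libraries. If that library alone drove the calls, most would be lost without it. Without it 83.4% of the 956 called genes were still called in the same direction, which argues against that explanation for the count as a whole. Leaving out any other single library kept 78.2% to 84.0%. Of the 175 genes called 2-fold, 81.1% were kept without deletion replicate 2, against 90.3% to 96.6% without any other library. The 2-fold calls thus depended more on deletion replicate 2 than on any other library. What set this library apart was not tested.

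The genes numbered just after the deleted gene, Clo1313_2034 to Clo1313_2038, rose by a median of 4.51 on the log2 scale, and transcription running on from the deletion site may explain part of it. The largest gain in that run, 1403 CPM at Clo1313_2038, was 3.21 times the larger gain of the genes in between, 437 CPM at Clo1313_2032, but gene lengths and strands were not analysed here, so the comparison leaves run-on open. A response of nitrogen genes wherever they lie is another candidate explanation. The 13 described nitrogen genes more than 100 locus tags away rose by a median of 5.14. All of them except Clo1313_2260 and Clo1313_2303 lie in the run Clo1313_2486 to Clo1313_2499, and the median is the value of Clo1313_2494 there. Neighbouring genes of a run may share transcripts, so the 13 may not be separate instances of a response. The nitrogen list was also described on these samples because its genes had changed, so this median cannot decide either. The explanations cannot be told apart for the 5 genes Clo1313_2034 to Clo1313_2038.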

How the results depend on the processing

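The fold of pooled reads of the deleted gene without each library was the only test in this part chosen only after the result was seen. The count of 956 called genes was 856 to 1064 over the changes of tool, scaling, filter, R tags and block, and 777 to 891 without 1 library. The count of 175 genes called 2-fold was 135 to 181 over the same changes, 180 by a test against a 1.5-fold limit and 157 to 206 without 1 library. Only 139 of the 180 genes were among the 175, so the near-equal totals cover partly different genes. Total-count scaling raised the share of calls that were higher from 50.3% to 58.3%. For 39 named genes under 16 settings, 606 results kept their direction and side of the threshold, 15 kept the direction but no longer passed, and 0 reversed. All 15 concerned Clo1313_2027 or Clo1313_2029, which also failed with limma-voom (adjusted p 0.0574 and 0.0527), with adjusted p-values over single left-out libraries of 0.0224 to 0.131 and 0.0271 to 0.102. The cause was not tested. The strict filter removed Clo1313_0959, Clo1313_2385 and Clo1313_2976. Calls shared with the authors' deposited table were 150 at 2-fold and 947 with no fold limit, since more genes enter. The deleted gene's mean in wild type was 354 CPM of all counts and 460 CPM without the 10 most abundant genes, since the total is smaller. Its pooled fold, 908, was 629 to 1641 without 1 library, highest without deletion replicate 4, which held 15 of the 27 reads, and its fitted log2 fold change was −10.63 to −9.30. In the simulation 55.8% of 1.5-fold changes were recovered, with 200 of 2954 genes changed, against 956 genes called here. Recovery in these data may differ from that, and small changes may have been missed. Camera, camera with an estimated correlation, fry and 1 gene per run of locus tags were not run.

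With the replicate number as a block, 968 genes were called and 176 at 2-fold, and Clo1313_2029 no longer passed (adjusted p 0.0694 by edgeR). Deviations of same-numbered libraries correlated at 0.175, −0.0286, 0.230 and 0.0209, and for numbers 1 and 3 alone was the own number the best match, so the numbers were not taken as paired.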

Other observations

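The tests of the summed glutamine synthetase reads, the copper amine oxidase-like genes and the near-silent genes were chosen only after the results were seen, while the test of adjacent genes was chosen before its result was seen. A run of 6 consecutively numbered genes, Clo1313_2096 to Clo1313_2101, fell by at least 2-fold each, with log2 fold changes of −2.02 to −1.07. Their descriptions are a 4'-phosphopantetheinyl transferase, a beta-ketoacyl synthase, a hypothetical protein, an AMP-dependent synthetase and ligase, a beta-ketoacyl-acyl-carrier-protein synthase I and a phosphopantetheine-binding protein, terms used for enzymes of fatty acid and polyketide assembly. Apart from Clo1313_2101 these genes were chosen after their values were seen. Beside the glutamine synthetase gene Clo1313_2303, the genes Clo1313_2304 and Clo1313_2305, described as B and A subunits of a glutamyl-tRNA(Gln) amidotransferase, rose by 1.23 ± 0.18 and 1.26 ± 0.16 on the log2 scale and were also chosen after their values were seen.

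Genes called in this comparison often stood side by side. Among 2815 pairs of consecutively numbered tested genes, 436 pairs had both genes called in the same direction, while 1000 shuffles of the calls gave 148 on average and 181 at most. Pairs called in opposite directions numbered 36, below the lowest shuffle of 120. Among the genes called 2-fold, 11 runs of at least 3 consecutive genes, 5 higher and 6 lower, held 54 of 167 numbered genes. Shared transcripts are a candidate explanation for the 436 pairs, and transcript boundaries were not analysed here.

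Summed over the 3 described glutamine synthetase genes, wild type had 474 ± 58.7 CPM and the deletion strain 1684 ± 157 CPM (SD, n = 4 each), and the lowest deletion sum was 3.69 times the lowest wild type sum. Clo1313_2031 held 75.6% of the sum in wild type and Clo1313_2038 held 90.0% in the deletion strain. The sum was 1494 to 1838 CPM in the deletion libraries and 405 to 529 CPM in wild type, so among these 3 genes the reads gained exceeded those lost. The 3 genes were described because they had changed in these libraries. Glutamine synthetase genes that changed by less than 2-fold could not enter the sum, so it gives no total over all such genes. CPM is not corrected for gene length, and transcript sums do not measure enzyme activity.

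The 6 described copper amine oxidase-like genes all fell, but 61 of the 144 other described genes fell too. Fisher's exact test gave p = 0.00698, and 0.0907 after adjustment over 13 families counted, so a direction shared beyond that of the described genes was not established. Since all 6 fell, no smaller unadjusted p was possible for a family of 6 here, so the test could hardly have passed.

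If the deletion strain also lacks hpt, which the labels do not state, the hpt locus might appear as a gene silent in all 8 libraries between expressed neighbours. There were 10 locus tags under 1.5 CPM in all libraries with neighbours of at least 50 CPM, so the reads alone did not single out 1 locus. Whether any of the 10 is hpt was not determined, since no description used here names that gene.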
